A study of Mus musculus with 27 samples.

How the data were processed

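RNA was sequenced from the colon of 27 BALB/c mice in 5 groups. NC were untreated mice (n = 6). The other 4 groups had been given azoxymethane and dextran sulfate sodium (AOM/DSS), a carcinogen and a chemical irritant of the colon, until inflammation-associated neoplasia had formed. They were CAC without further treatment (n = 5), CAC_F with FOLFOX, a chemotherapy of folinic acid, fluorouracil and oxaliplatin (n = 5), CAC_FP with FOLFOX and a probiotic complex (n = 5), and CAC_FPL with FOLFOX, the probiotic complex and loperamide, an opioid receptor agonist that slows the gut (n = 6). Tissue was taken 1 week after chemotherapy began. Per the labels the NC tissue was colon and that of the other groups a tumor-bearing segment of colon, so tissue source and AOM/DSS exposure coincide, and 1 batch was given for the libraries. Total RNA was extracted with Trizol, and stranded mRNA libraries were made with the dUTP method.

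The deposited table holds raw counts per gene, whole numbers with 1 column per library, for 39971 genes. Beside the counts the authors give FPKM, fragments per kilobase of gene model and per unit of library depth, with 2 decimals. The submitters' processing notes name cutadapt 1.9, FastQC and HISAT2. Their roles, the counting tool, the annotation and the genome build are not given in the sources used here. Total counts were 56687812 to 79709845 per library, and 99.3% of counts fell in the genes tested. Reads that fit several gene copies appeared to be counted at each copy: the nuclear copy Gm28437 held 96.2% to 100% of the counts of mt-Co3 in each library. No reference genome was used.

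The groups, comparisons, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. That plan expected FPKM alone and named edgeR's quasi-likelihood test for the case that the table held whole counts, and this test was used. Genes with an FPKM of at least 1 in at least 5 of the 27 libraries were kept (15080 genes). Counts were scaled with trimmed means of M values (TMM), and 1 model with a coefficient per group was fitted to all 27 libraries with edgeR 4.0.16 in R 4.3.3. Genes were called at an adjusted p below 0.05 after Benjamini-Hochberg adjustment over the 15080 genes. Log2 fold changes are given ± a standard error (SE) derived from the test. It is the absolute log2 fold change over the square root of the quasi-likelihood F statistic. This SE is approximate, above all where a group is near 0 counts. Levels are counts-per-million (CPM) over TMM-scaled libraries, as mean ± SD. Where every library of a group was at 0, the fold is a lower bound against 3 counts over the group. For groups with 1 to 3 counts a ratio with its 95% exact Poisson interval is given. Intervals and floors cover counting error only.

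Of 39 gene lists for colon cell types, metabolism, treatment responses and possible admixed tissues, the 36 with at least 5 measured members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. camera with the correlation estimated per list and fry were run beside it. Camera compares a list with other genes, whereas fry asks whether the members move, on balance, one way. The 4 main comparisons were CAC with NC, CAC_F with CAC, CAC_FP with CAC_F and CAC_FPL with CAC_FP, and 5 further ones are given as counts and lists. All tests were two-sided.

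Named genes followed a fixed rule. In each main comparison it took the 10 largest positive and 10 largest negative log2 fold changes among called genes of at least 2-fold whose groups did not overlap, leaving out predicted genes, immunoglobulin and T cell receptor segments. Where none passed in a direction, it took the 5 smallest unadjusted p among genes with a mean FPKM of at least 1, as values. From each list discussed it took up to 4 called members with the smallest adjusted p, or up to 2 with the smallest unadjusted p. It always took 13 further genes: Nampt, Nmnat1, Nmrk1, Naprt, Cd38, Nnmt, Cdkn1a, Mki67, Lgr5, Muc2, Slc26a3, Il1b and S100a8. Fewer members were printed where a sentence gives fewer.

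The alternatives fixed in advance were no filter, a mean FPKM of at least 5, median-ratio size factors, voom with library weights, a robust prior, a replicate block, the mean of the smooth muscle list as a covariate, a fit of only the groups compared, each library left out in turn, and limma on log2(FPKM + 0.1) and on quantile-normalized log2(FPKM + 1). Limma on log2(FPKM + 1), the test that plan named for FPKM alone, was kept as an alternative once the table was seen to hold counts. Voom with quantile normalization, DESeq2 1.42.0 and a fit without CAC replicate 2 and CAC_FPL replicate 3 were added after seeing the data. The libraries of each comparison were also divided in other ways, 25 per comparison with the real one, a number lowered for running time before any such result was seen. The agreement of CAC_F and CAC_FP against CAC under shared CAC libraries and simulations with divided libraries were added after the results were seen. All simulations drew each gene independently, so variation that many genes share between libraries is not in their ranges. The pipeline was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 62% to 71% of the former and 90% or 91% of the latter in the 4 main comparisons, with 5 to 11 false calls among 157 to 172. The counts of replicates of one group differed far beyond sampling noise in all 60 pairs, with a chi-square per degree of freedom of at least 83.3, so each library was counted as 1 sample. Figures were drawn with matplotlib 3.10.9.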

Results

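Gene expression was measured by RNA sequencing in colon tissue of 27 mice: 6 untreated mice (NC), 5 with AOM/DSS-induced neoplasia (CAC), 5 with neoplasia and FOLFOX (CAC_F), 5 that also received a probiotic complex (CAC_FP) and 6 that received loperamide as well (CAC_FPL). Total counts per library were 60327257 to 79709845 in NC, 56687812 to 71260166 in CAC, 61433532 to 77206403 in CAC_F, 63276601 to 72343614 in CAC_FP and 67336922 to 76966764 in CAC_FPL. Between 24499 and 27362 genes had counts in a library. The series title names NAD+ metabolism, so genes that make and use this redox cofactor are followed through every comparison.

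The first principal component held 38.1% of the variance of log2 expression and the second 10.6%. On the first component NC lay at -54.3 ± 3.83 (SD, n = 6), CAC at -43.5 ± 17.1 (n = 5), CAC_F at 61.1 ± 18.8 (n = 5), CAC_FP at 36.9 ± 21.8 (n = 5) and CAC_FPL at 8.9 ± 31.2 (n = 6). Transcripts of mitochondrial genes held 6.71% ± 1.18 of counts in NC, 8.48% ± 2.79 in CAC and 4.58% ± 0.48 in CAC_F.

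**Figure D1:**
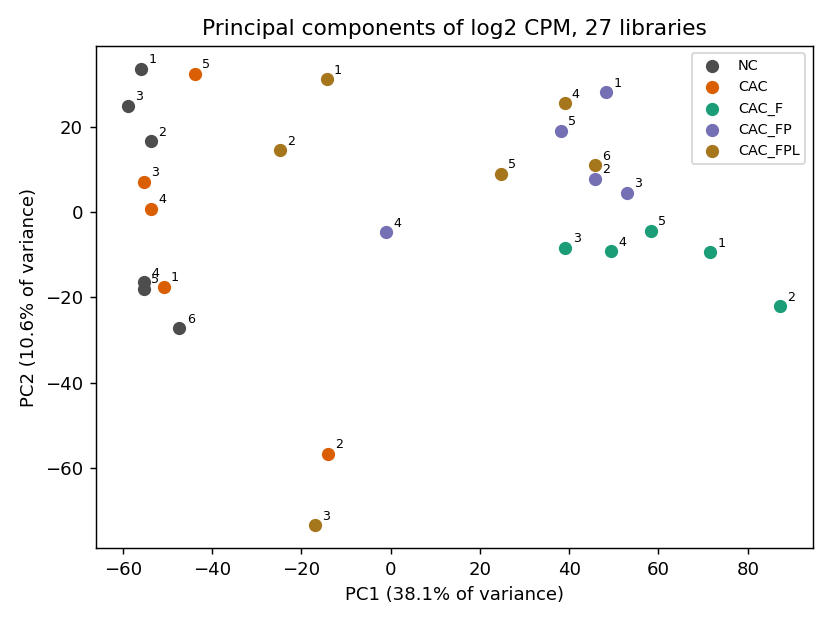
First and second principal components of log2 CPM for the 27 libraries, 1 point per library, colored by group and numbered by replicate. NC and CAC libraries lay between -58.7 and -14.0 on the first component and CAC_F libraries between 39.2 and 87.2.

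The comparison of CAC with NC asks what AOM/DSS-induced neoplasia changed, with the tissue source changing along with it. Cry1, a repressor of the circadian clock, was lower in CAC, at 16.5 ± 2.14 CPM (SD, n = 5) against 28.3 ± 5.02 CPM (n = 6). Its log2 fold change was -0.78 ± 0.12 (SE; adjusted p = 0.0121, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). It lies on chromosome 10 from 84967564 to 85020928 in the deposited coordinates, whose build is not given in the sources used here. Cry1 fell and no other of the 15080 genes passed the test. The genes next in order had an adjusted p of 0.142 or above by the edgeR quasi-likelihood test. Their log2 fold changes were 2.34 ± 0.47 for Gpnmb, a glycoprotein of macrophages, 1.37 ± 0.29 for the clock activator Bmal1, 1.01 ± 0.21 for the phosphatase Cdc14b, 0.62 ± 0.13 for Zdhhc15 and 0.31 ± 0.065 for Clcc1. Those on the lower side were -0.69 ± 0.14 for the stress kinase Plk3, -0.69 ± 0.15 for Metrnl, -0.37 ± 0.082 for Pitpnm1 and -0.47 ± 0.11 for Elovl1.

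Several lists differed between CAC and NC as sets under the preset correlation, although Cry1 was the sole called member of any. Besides those described below, cell type lists called were tuft, cytotoxic and NK, B and plasma, macrophage and monocyte, and fibroblast. Enteric neuron and glia, adipocyte, and small intestine and Paneth cell lists were called too. These calls were lost with an estimated correlation (camera adjusted p = 0.523 to 0.655) and with fry (adjusted p = 0.431 to 0.616). The proliferation list was higher (camera adjusted p = 2.86e-05; adjusted p = 0.655 with an estimated correlation), with positive log2 fold changes in 23 of 28 members such as Cenpa at 0.66 ± 0.24 and Bub1 at 0.60 ± 0.25. The goblet cell list was lower (camera adjusted p = 1.25e-05; adjusted p = 0.584 with an estimated correlation), with 1 of 17 members positive. Retnlb was at -1.68 ± 0.68 and the mucus regulator Clca1 at -1.24 ± 0.54. Absorptive colonocyte genes were lower as a list (camera adjusted p = 9.43e-05; adjusted p = 0.584 with an estimated correlation), with Krt20 at -1.02 ± 0.28 and Vil1 at -0.59 ± 0.18. In it 2 members were lower when adjusted over the list alone. Glycolysis and hypoxia genes were lower as a list (camera adjusted p = 1.09e-06; adjusted p = 0.523 with an estimated correlation), with Hk1 at -0.43 ± 0.15 and Ldha at -0.38 ± 0.15. The circadian clock list was lower (camera adjusted p = 0.00203; adjusted p = 0.523 with an estimated correlation), with 2 higher and 3 lower members of 16 when adjusted over the list alone. The antimicrobial peptide genes Reg3b and Reg3g were at 3.83 ± 0.85 and 2.92 ± 0.73, and their list did not pass (camera adjusted p = 0.953). In it 3 members were higher and 1 lower when adjusted over the list alone.

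NAD-related genes did not pass in this comparison. The NAD biosynthesis list had an adjusted p of 0.133 by camera and the NAD consumption list 0.425. Log2 fold changes were -0.40 ± 0.16 for Nampt, the rate-limiting enzyme of NAD salvage from nicotinamide, -0.041 ± 0.13 for Nmnat1, 0.27 ± 0.18 for the nicotinamide riboside kinase Nmrk1, -0.094 ± 0.21 for Naprt, which starts NAD synthesis from nicotinic acid, -0.076 ± 0.28 for the NAD hydrolase Cd38 and -0.72 ± 0.77 for Nnmt. Others always followed were at -0.64 ± 0.22 for the cell cycle inhibitor Cdkn1a, 0.39 ± 0.22 for the proliferation marker Mki67, -0.29 ± 0.52 for the mucin Muc2, -0.72 ± 0.59 for the chloride exchanger Slc26a3, 1.13 ± 0.71 for Il1b and 2.90 ± 1.19 for the neutrophil protein S100a8. Over all alternatives the log2 fold change of S100a8 ran from 0.062 to 3.62. The stem cell marker Lgr5 was under the filter, at 3.37 ± 0.721 CPM in NC and 3.43 ± 1.91 CPM in CAC.

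The call of Cry1 was lost without NC replicate 2 (adjusted p = 0.0522), NC replicate 6 (0.0541), CAC replicate 4 (0.0662) or CAC replicate 5 (0.0875) and in a fit of only these groups (0.231), all by edgeR. Cdc14b passed without NC replicate 4 (0.0258) or NC replicate 5 (0.0255) and Plk3 without NC replicate 3 (0.0473) or NC replicate 5 (0.0481), by edgeR. At an unadjusted p below 0.05 there were 1164 genes where chance gives 754, and DESeq2 called 41 genes. Cdc14b, Clcc1 and Pitpnm1 passed with DESeq2 and in voom with library weights. In all, 165 genes (1.09%) had groups that did not overlap, where chance gives 0.433%.

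**Figure D2:**
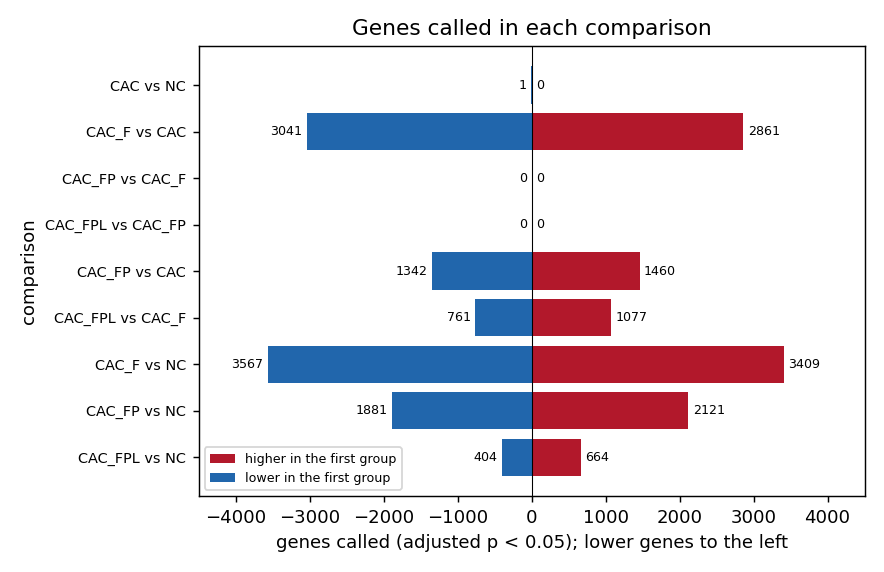
Number of genes called in each of the 9 comparisons at an adjusted p below 0.05, with genes higher in the first group to the right and genes lower to the left. CAC_F against CAC had 2861 higher and 3041 lower genes.

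The comparison of CAC_F with CAC asks what FOLFOX changed in the tumor-bearing colon. Hoxa13, taken below as a marker of a more distal segment, was at 1.60 to 27.1 CPM in the CAC_F libraries. In CAC it was at 37.2 CPM in replicate 2 and at 2.30 to 6.04 CPM in the others. Mean Hoxd11 was 3.54 CPM in CAC_F and 5.91 CPM in CAC. Whether segment position differed between CAC_F and CAC was not tested. Of 15080 genes, 2861 rose and 3041 fell (edgeR quasi-likelihood test, adjusted p below 0.05), 817 and 960 of them by at least 2-fold. The p53 response, proliferation and inflammatory lists were higher and goblet cell, smooth muscle and MHC class II lists lower by camera at the preset correlation. With an estimated correlation all 6 of these calls were lost (camera adjusted p = 0.12 to 0.681). Rrm2, the ribonucleotide reductase subunit that supplies DNA synthesis, was at 188 ± 13.2 CPM (SD, n = 5) against 32.5 ± 17.8 CPM (n = 5), and Clca1 at 398 ± 223 CPM against 9260 ± 6880 CPM. Cdkn1a was at 240 ± 61.7 CPM against 95.9 ± 15.5 CPM.

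The granulocyte growth factor Csf3 rose by a log2 fold change of 11.26 ± 2.23, from 0.0367 ± 0.0821 CPM to 90 ± 120 CPM, a spread among the CAC_F libraries of 1.04 to 268 CPM. In CAC it had 11 counts in replicate 3 and 0 in the other libraries, so the base of this fold rests on that library. Over all alternatives the log2 fold change of Csf3 ran from 4.07 to 15.58. The neutrophil chemokines Cxcl1 and Cxcl2 rose by 8.88 ± 1.80 and 8.34 ± 1.86, the protease Prss22 by 8.40 ± 0.97, the keratins Krt4 and Krt6a by 7.88 ± 1.15 and 7.26 ± 1.44, the protease inhibitor Spink6 by 7.37 ± 1.23 and Gml by 7.89 ± 1.52. Gml2 was at 0 in every CAC library and at least 470-fold higher in CAC_F. Reg3d had 2 counts over the CAC libraries and 1361 over those of CAC_F, a ratio of 637 with a 95% counting interval of 176 to 5270.

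The largest falls were in haemoglobin genes. Hbb-bs and Hbb-bt were at 0 in every CAC_F library, at least 4370-fold and 1050-fold lower than in CAC, and Hba-a1 and Hba-a2 had log2 fold changes of -9.45 ± 1.52 and -9.34 ± 1.54. Summed haemoglobin transcripts were at 0.197 ± 0.126 CPM (SD, n = 5) in CAC_F, 94.8 ± 91.8 CPM (n = 5) in CAC and 36.5 ± 10.4 CPM (n = 6) in NC. Gnat3, a taste G protein of tuft cells, was at 0 in CAC_F and at least 117-fold lower. Epithelial genes followed. Their log2 fold changes were -7.62 ± 1.31 for the mucosal pentraxin Mptx1, -7.04 ± 1.27 for Mptx2, -7.17 ± 1.09 for the gasdermin Gsdmc4, -6.93 ± 1.32 for the phospholipase Pla2g4c and -6.84 ± 1.14 for Otc, a urea cycle enzyme.

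In the p53 response list 19 of 26 members rose and none fell (camera adjusted p = 8.43e-12; adjusted p = 0.12 with an estimated correlation). Plk3 rose by a log2 fold change of 1.19 ± 0.14, the pro-apoptotic Bax by 1.26 ± 0.17, Ddit4 by 1.44 ± 0.20, Zmat3 by 1.13 ± 0.16 and Cdkn1a by 1.33 ± 0.23 (adjusted p = 0.000181, edgeR). In the proliferation list 23 of 28 members rose (camera adjusted p = 1.6e-09; adjusted p = 0.664 with an estimated correlation), among them the S phase genes Ccne1 at 1.67 ± 0.28, Rrm2 at 2.53 ± 0.44, Mcm4 at 1.32 ± 0.25 and Mcm3 at 1.42 ± 0.29. Mki67 rose by 0.58 ± 0.23 (adjusted p = 0.0467, edgeR), and its adjusted p was 0.0512 to 0.117 without CAC replicate 1, 3, 4 or 5 or without CAC_F replicate 1, 3, 4 or 5. The call was also lost with no filter (0.0737), with voom and quantile normalization (0.0713), with only these groups in the fit (0.063) and with the smooth muscle covariate, which left 0.27 (adjusted p = 0.459, edgeR). Of 16 Nrf2 targets, which answer oxidative stress, 11 rose and 2 fell (camera adjusted p = 6.75e-05; adjusted p = 0.521 with an estimated correlation), with Txnrd1 at 1.04 ± 0.15, Gsta4 at 1.27 ± 0.19 and Hmox1 at 1.97 ± 0.30. Of 19 glycolysis and hypoxia genes 7 rose and 2 fell (camera adjusted p = 0.0117; adjusted p = 0.664 with an estimated correlation and 0.106 with the smooth muscle covariate), with Pkm at 1.13 ± 0.14 and Hk2 at 1.79 ± 0.28.

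Inflammatory cytokines and proteases rose in 19 of 21 members (camera adjusted p = 4.88e-08; adjusted p = 0.664 with an estimated correlation), including the collagenase Mmp13 at 3.71 ± 0.69, the monocyte attractant Ccl2 at 6.64 ± 1.28, Il1a at 4.97 ± 0.96 and Il11 at 5.68 ± 1.11. The size of these changes rests partly on CAC_F replicates 1 and 2. The mean log2 CPM of the inflammatory cytokines and proteases list was 5.76 in CAC_F replicate 1 and 6.10 in CAC_F replicate 2, 1.89 to 3.38 in the other CAC_F libraries and 0.42 to 1.24 in CAC. The neutrophil attractant Cxcl1 was at 778 and 319 CPM in CAC_F replicates 1 and 2 and at 2.64 to 20.6 CPM in the other CAC_F libraries. Il1b rose by 2.86 ± 0.79, a call lost with voom and quantile normalization (adjusted p = 0.0535; 0.000229 to 0.0535 over all alternatives). Of 8 neutrophil genes 5 rose (camera adjusted p = 0.0375; adjusted p = 0.664 with an estimated correlation and 0.174 with the smooth muscle covariate), with Ly6g at 5.00 ± 1.17 and Mmp9 at 1.77 ± 0.45. S100a8 rose by 2.94 ± 1.14 (adjusted p = 0.0431, edgeR), and its adjusted p was 0.0804 to 0.0961 without CAC replicate 1, 3, 4 or 5 or without CAC_F replicate 2 or 4. The call was also lost with no filter (0.0894), with only these groups in the fit (0.11) and with the smooth muscle covariate, which left 1.28 (adjusted p = 0.403, edgeR). Over all alternatives the log2 fold change of S100a8 ran from 1.28 to 6.41. Its adjusted p, by the test of each alternative, ran from 0.000218 to 0.403. Of 18 macrophage and monocyte genes 10 rose and 2 fell (camera adjusted p = 0.0119; adjusted p = 0.716 with an estimated correlation), with the mannose receptor Mrc1 at 2.10 ± 0.41 and the endotoxin receptor Cd14 at 1.82 ± 0.37. Antimicrobial and epithelial defence genes rose in 7 of 16 members and fell in 3, among them Pla2g2a at 3.50 ± 0.54 and Reg3g at 4.09 ± 0.82, and the list did not pass by camera (adjusted p = 0.0667).

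Some lymphoid, interferon and antigen presentation genes fell, where 3041 of all 15080 genes did. MHC class II presentation genes fell in 8 of 11 members (camera adjusted p = 0.00576; adjusted p = 0.681 with an estimated correlation), with H2-Aa at -1.81 ± 0.33 and H2-Eb1 at -1.78 ± 0.35. Interferon response genes fell in 13 of 25 (camera adjusted p = 0.0102; adjusted p = 0.756 with an estimated correlation and 0.0849 with fry), with Mx1 at -2.38 ± 0.42 and Irf7 at -1.82 ± 0.36. T cell genes fell in 8 of 18 (camera adjusted p = 0.0238; adjusted p = 0.77 with an estimated correlation and 0.0984 with fry), with Cd8b1 at -1.89 ± 0.48 and Cd3g at -1.55 ± 0.40. B and plasma cell genes fell in 5 of 20 (camera adjusted p = 0.0119; adjusted p = 0.756 with an estimated correlation, 0.0825 with fry and 0.0607 with voom and quantile normalization), with the plasma cell receptor Tnfrsf17 at -2.50 ± 0.40 and Derl3 at -1.43 ± 0.30.

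Goblet cell genes fell in 11 of 17 members (camera adjusted p = 5.31e-06; adjusted p = 0.664 with an estimated correlation), with Clca1 at -4.54 ± 0.64, the secretory transcription factor Creb3l1 at -1.84 ± 0.28, Tpsg1 at -2.23 ± 0.49 and Retnlb at -3.21 ± 0.74. The main mucin Muc2 was at -0.88 ± 0.55 and was not called. Of 9 tuft cell genes 5 fell and 2 rose (camera adjusted p = 0.079), with the cation channel Trpm5 at -3.03 ± 0.53, Sh2d6 at -2.85 ± 0.53 and Avil, an actin regulator of tuft cells, at 1.73 ± 0.29. Slc26a3 was at -1.08 ± 0.62, not called, but passed with the smooth muscle covariate at -2.04 (adjusted p = 0.0449, edgeR; 0.0449 to 0.332 over all alternatives). Lgr5 was at 0.637 ± 0.508 CPM (SD, n = 5) against 3.43 ± 1.91 CPM (n = 5), under the filter. Smooth muscle genes, markers of the gut wall in the sample, fell in 15 of 16 members (camera adjusted p = 6.81e-06; adjusted p = 0.664 with an estimated correlation), with Actg2 at -2.37 ± 0.44 and Des at -1.91 ± 0.39. With the smooth muscle score as a covariate 4646 genes were called, 3680 of them shared with the 5902, and the call of Des was lost (adjusted p = 0.0743, edgeR).

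**Figure D3:**
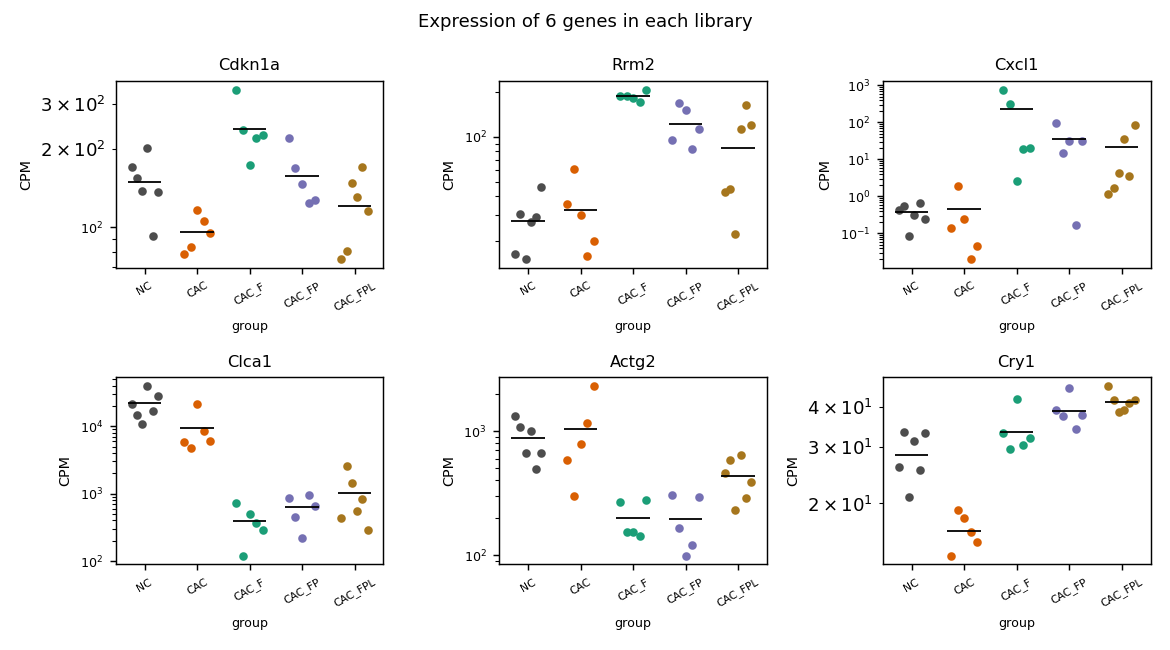
CPM on log axes of the p53 target Cdkn1a, the S phase gene Rrm2, the chemokine Cxcl1, the goblet gene Clca1, the smooth muscle gene Actg2 and the clock gene Cry1 in each library, 1 point per library, with group means as lines and values under 0.02 drawn at 0.02. Rrm2 was between 171 and 208 CPM in the CAC_F libraries and between 15.9 and 61.1 CPM in those of CAC.

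NAD genes moved in both directions after FOLFOX, in a comparison where 39.1% of all genes were called. Neither NAD list passed by camera. Of 14 measured NAD biosynthesis genes 3 rose and 5 fell (camera adjusted p = 0.54), or 4 and 5 when adjusted over the list alone. Naprt fell from 45.1 ± 8.05 CPM (SD, n = 5) to 22.1 ± 5.99 CPM (n = 5), by a log2 fold change of -1.03 ± 0.23 (adjusted p = 0.00121, edgeR). The NAD synthetase Nadsyn1 was at -1.07 ± 0.22 and Nnt, the mitochondrial transhydrogenase that couples NADH to NADPH, at -0.58 ± 0.086, both called, and Pnp rose by 0.63 ± 0.18. The call of Pnp was lost with the smooth muscle covariate, which left 0.43 (adjusted p = 0.12, edgeR; 0.000738 to 0.12 over all alternatives). Nampt was at 0.19 ± 0.16, Nmnat1 at 0.16 ± 0.14 and Nmrk1 at -0.20 ± 0.19, none of them called. Of 22 NAD consumption genes 1 rose and 4 fell (camera adjusted p = 0.596). Cd38 rose by 1.62 ± 0.30, from 130 ± 48.6 CPM to 399 ± 150 CPM, whereas the sirtuins Sirt3, Sirt1 and Sirt7 fell, at -0.86 ± 0.18, -0.58 ± 0.14 and -0.36 ± 0.10. The call of Sirt7 was lost with no filter (adjusted p = 0.056, edgeR; 0.00353 to 0.056 over all alternatives). Nnmt was at -0.067 ± 0.80, not called. In the circadian clock list 3 of 16 members rose and 4 fell (camera adjusted p = 0.692), with Cry1 at 1.02 ± 0.12 and the repressor Nr1d1 at -2.07 ± 0.34. Mean Cry1 was 28.3 CPM in NC, 16.5 CPM in CAC and 33.4 CPM in CAC_F. A different time of day at collection, raised below for CAC and NC, was not tested for CAC_F and CAC and would coincide with the groups.

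With an estimated correlation camera called 0 lists in this comparison. Fry called 15, but not the interferon response, T cell and B and plasma cell lists that camera had called, and it called tuft cells, antimicrobial and epithelial defence, and opioid and serotonin signalling (adjusted p = 0.00997, 0.0113 and 0.00575), which camera had not. With a mean FPKM of at least 5 required, 3708 genes were called, and 3132 genes (20.8%) had groups that did not overlap, where chance gives 0.794%.

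**Figure D4:**
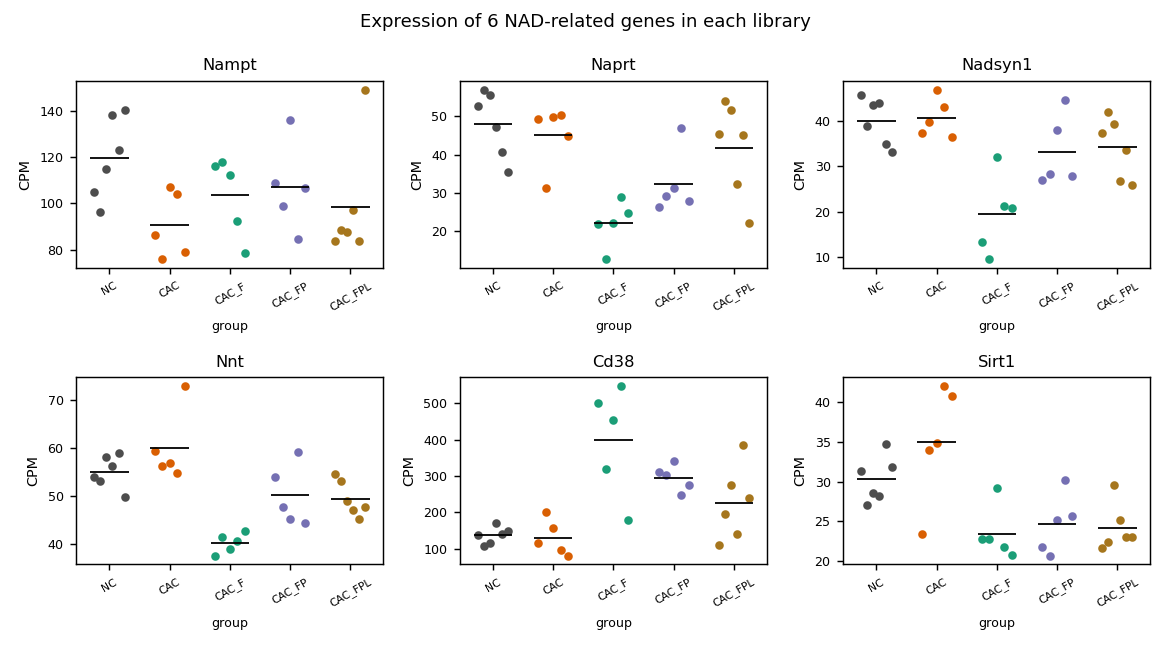
CPM of Nampt, Naprt, Nadsyn1, Nnt, Cd38 and Sirt1 in each library on linear axes, 1 point per library, with group means as lines. Mean Naprt was 48.2 CPM in NC, 45.1 in CAC, 22.1 in CAC_F, 32.3 in CAC_FP and 41.8 in CAC_FPL.

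The comparison of CAC_FP with CAC_F asks what the probiotic complex changed on top of FOLFOX. Hoxa13, taken below as a marker of a more distal segment, was at 14.8 ± 9.42 CPM in CAC_F, with libraries from 1.60 to 27.1 CPM. In CAC_FP it was at 2.23 ± 1.33 CPM, with libraries from 0.538 to 3.83 CPM. Hoxd11 was at 3.54 ± 1.01 CPM in CAC_F and 6.15 ± 3.03 CPM in CAC_FP. Whether segment position differed between these groups was not tested. As a set, NAD biosynthesis genes were higher with the probiotic complex, with positive log2 fold changes in 12 of 14 members (camera adjusted p = 0.00832; adjusted p = 0.367 with an estimated correlation; fry adjusted p = 0.00829). Nnt, the transhydrogenase that couples NADH to NADPH rather than making NAD, was at 0.31 ± 0.086 and Nadsyn1 at 0.78 ± 0.22. These 2 list members were higher when adjusted over the list alone. Inflammatory and p53 response lists were lower and the goblet cell list higher by camera at the preset correlation. These 3 calls were lost with an estimated correlation (adjusted p = 0.716, 0.531 and 0.716) and with fry (adjusted p = 0.366, 0.0978 and 0.366). No gene was called over all 15080 (edgeR quasi-likelihood test, smallest adjusted p = 0.119). Naprt was at 32.3 ± 8.41 CPM (SD, n = 5) against 22.1 ± 5.99 CPM (n = 5), a log2 fold change of 0.55 ± 0.22 (adjusted p = 0.24, edgeR). Single libraries carry part of these gene differences, as was seen only on looking at the values. CAC_FP replicate 4 held the highest Naprt of its group (47.0 CPM, others 26.4 to 31.3), the highest Nadsyn1 (44.6 CPM, others 26.9 to 38.0) and the highest Nnt (59.1 CPM, others 44.3 to 54.0). Nadsyn1 was lowest in CAC_F replicates 1 and 2 (13.2 and 9.44 CPM, others 20.9 to 32.1), and Naprt in CAC_F replicate 2 (12.6 CPM, others 21.9 to 29.0). The mean log2 CPM of the NAD biosynthesis list was 5.19 in CAC_FP replicate 4, 5.18 to 5.28 over CAC_FP and 4.77 to 5.13 over CAC_F.

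The genes with the smallest p on the higher side were the dendritic cell lectin Cd209a at 3.13 ± 0.62, Otc at 4.86 ± 1.06, the histamine-degrading Aoc1 at 1.57 ± 0.34, Tssk4 at 1.49 ± 0.32 and Leng1 at 0.58 ± 0.12. On the lower side they were Ptgs2, the inducible prostaglandin synthase, at -4.24 ± 0.92, Arih2 at -0.62 ± 0.13, Hddc2 at -0.61 ± 0.12, Tatdn2 at -0.59 ± 0.11 and Commd10 at -0.43 ± 0.087. Ptgs2 was at 120 ± 155 CPM in CAC_F, with libraries from 6.21 to 321 CPM, and at 6.34 ± 1.99 CPM in CAC_FP. CAC_F replicates 1 and 2 stood apart, with Ptgs2 at 321 and 255 CPM, Csf3 at 268 and 161 CPM and Cxcl1 at 778 and 319 CPM. The other 3 CAC_F libraries had Ptgs2 at 6.21 to 10.5 CPM, Csf3 at 1.04 to 11.1 CPM and Cxcl1 at 2.64 to 20.6 CPM, near or within the CAC_FP range. For these genes the difference between the groups thus rests on 2 of 5 libraries, as noticed after the values were seen.

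The p53 response list was lower (camera adjusted p = 1.56e-05; adjusted p = 0.531 with an estimated correlation), with 3 of 26 members positive, Plk2 at -1.13 ± 0.28, Ddit4 at -0.62 ± 0.20 and Cdkn1a at -0.60 ± 0.23. Inflammatory cytokines and proteases were lower (camera adjusted p = 0.000164; adjusted p = 0.716 with an estimated correlation), 6 of 21 members being lower when adjusted over the list alone, with Mmp13 at -2.51 ± 0.66 and Il1b at -1.83 ± 0.76. The mean log2 CPM of the inflammatory cytokines and proteases list was 5.76 in CAC_F replicate 1 and 6.10 in CAC_F replicate 2, 1.89 to 3.38 in the other CAC_F libraries and 1.14 to 3.87 in CAC_FP. Neutrophil genes were lower (camera adjusted p = 0.0103; adjusted p = 0.716 with an estimated correlation), 4 of 8 when adjusted over the list alone, with S100a9 at -3.69 ± 1.29 and S100a8 at -3.16 ± 1.15. Goblet cell genes were higher (camera adjusted p = 0.00232; adjusted p = 0.716 with an estimated correlation), with 16 of 17 positive, Creb3l1 at 0.69 ± 0.27, Atoh1, the secretory fate factor, at 1.08 ± 0.44 and Muc2 at 0.46 ± 0.54. Absorptive colonocyte genes were higher (camera adjusted p = 0.0103; adjusted p = 0.716 with an estimated correlation), with Guca2a at 1.39 ± 0.38, Cyp2c55 at 2.6 ± 0.99 and Slc26a3 at 0.0064 ± 0.61. Fatty acid oxidation and ketogenesis genes were higher (camera adjusted p = 0.00763; adjusted p = 0.716 with an estimated correlation), with Acadm at 0.59 ± 0.20 and its regulator Ppara at 1.23 ± 0.48. Proliferation genes were lower (camera adjusted p = 0.00763; adjusted p = 0.755 with an estimated correlation), with Cdk1 at -0.49 ± 0.26, Tk1 at -0.29 ± 0.18 and Mki67 at -0.28 ± 0.23. The smooth muscle list did not pass (camera adjusted p = 0.824). Enteroendocrine, tuft, B and plasma cell, macrophage and monocyte, and enteric neuron and glia lists were also called at the preset correlation. So were mitochondrial respiration, Nrf2 target, immediate early and ribosomal protein lists. All these calls were lost with an estimated correlation (camera adjusted p = 0.716 or 0.755) and with fry (adjusted p = 0.366 to 0.639).

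The remaining NAD genes were at 0.048 ± 0.16 for Nampt, 0.21 ± 0.14 for Nmnat1, 0.16 ± 0.19 for Nmrk1, -0.44 ± 0.29 for Cd38 and 1.34 ± 0.81 for Nnmt, and the NAD consumption list had a camera adjusted p of 0.0753. Lgr5 was at 2.02 ± 1.79 CPM in CAC_FP. The count of 0 genes became 616 without CAC_F replicate 3 and 3 without CAC_F replicate 5. Nadsyn1, Ptgs2, Cd209a, Otc and Guca2a were among the named genes that passed without CAC_F replicate 3. At an unadjusted p below 0.05 there were 2401 genes where chance gives 754, DESeq2 called 238 genes and voom with library weights 38, with Leng1, Tatdn2, Hddc2, Commd10 and Arih2 among the 38. In 2.31% of genes the groups did not overlap, where chance gives 0.794%.

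The comparison of CAC_FPL with CAC_FP asks what loperamide changed on top of FOLFOX and the probiotic complex. Haemoglobin genes had the smallest p on the higher side, with summed transcripts of 44.7 ± 67.4 CPM (SD, n = 6) against 0.218 ± 0.118 CPM (n = 5), and the CAC_FPL libraries ran from 0.0621 to 174 CPM. The 6 libraries did not form a single cluster. Replicates 1 to 3 lay at -24.9 to -14.3 on the first principal component, with haemoglobin at 32.2 to 174 CPM and Rrm2 at 22.3 to 45 CPM. Replicates 4 to 6 lay at 24.8 to 45.8, with haemoglobin at 0.0621 to 3.6 CPM and Rrm2 at 113 to 165 CPM. This division was noticed after the values were seen, the labels used here do not explain it, and group differences below average over it. Proliferation and p53 response lists were lower in CAC_FPL, and MHC class II, smooth muscle, B and plasma cell and T cell lists were higher, by camera at the preset correlation. These 6 calls were lost with an estimated correlation (adjusted p = 0.745 to 0.796) and with fry (adjusted p = 0.685 to 0.796). No single gene was called (edgeR quasi-likelihood test, smallest adjusted p = 0.113).

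Log2 fold changes were 8.05 ± 1.43 for Hba-a1, 6.95 ± 1.34 for Hba-a2 and 9.49 ± 1.83 for Hbb-bs. Hbb-bt had 3 counts over the CAC_FP libraries and 1873 over those of CAC_FPL, a ratio of 502 with a 95% counting interval of 172 to 2440. The monocyte chemokine receptor Ccr2 followed at 1.9 ± 0.43, and the genes on the lower side were Dpp9 at -0.41 ± 0.093, Cdkl2 at -0.46 ± 0.12, Tomm6 at -0.98 ± 0.27, Lgals2 at -3.85 ± 1.09 and the clock gene Npas2 at -0.86 ± 0.24. Lgals2 was at 0.87 without CAC_FP replicate 3.

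The proliferation list was lower with 0 of 28 members positive (camera adjusted p = 1.63e-10; adjusted p = 0.745 with an estimated correlation), with Cenpa at -0.45 ± 0.24, Kif11 at -0.40 ± 0.24 and Mki67 at -0.35 ± 0.22. The p53 response list was lower (camera adjusted p = 5e-05; adjusted p = 0.745 with an estimated correlation), with Ccng1 at -0.60 ± 0.18, Mdm2 at -0.36 ± 0.12 and Cdkn1a at -0.39 ± 0.21. MHC class II genes were higher, all 11 positive and 5 higher when adjusted over the list alone (camera adjusted p = 2.23e-08; adjusted p = 0.745 with an estimated correlation), with H2-Aa at 0.96 ± 0.32 and H2-Eb1 at 0.97 ± 0.33. Smooth muscle genes were higher with all 16 positive (camera adjusted p = 2.1e-06; adjusted p = 0.745 with an estimated correlation), with Actg2 at 1.14 ± 0.41 and Cnn1 at 1.01 ± 0.39. B and plasma cell genes were higher with all 20 positive (camera adjusted p = 0.000826; adjusted p = 0.796 with an estimated correlation), with Tnfrsf17 at 0.91 ± 0.37 and Cd79b at 1.65 ± 0.78. T cell genes were higher with 17 of 18 positive (camera adjusted p = 0.0044; adjusted p = 0.796 with an estimated correlation). Without CAC replicate 2 and CAC_FPL replicate 3 the camera adjusted p was 0.184 for B and plasma cells and 0.261 for T cells, and with a mean FPKM of at least 5 it was 0.0724 for B and plasma cells. Ion and water transport genes were higher (camera adjusted p = 0.0123; adjusted p = 0.796 with an estimated correlation and 0.0809 without CAC replicate 2 and CAC_FPL replicate 3), with the proton pump Atp12a at 4.59 ± 1.51, or -0.46 without CAC_FPL replicate 3, and the water channel Aqp4 at 3.98 ± 1.35. The circadian clock list was higher (camera adjusted p = 0.0123; adjusted p = 0.745 with an estimated correlation and 0.051 with the smooth muscle covariate), with 5 higher and 2 lower members when adjusted over the list alone and Bhlhe41 at 1.04 ± 0.30. Time of day at collection was not tested for CAC_FPL and CAC_FP. Goblet cell and inflammatory cytokine and protease lists were also called at the preset correlation. Each was lost with an estimated correlation (camera adjusted p = 0.796) and with fry (adjusted p = 0.796). The goblet cell call was also lost with the smooth muscle covariate (camera adjusted p = 0.0717). Opioid and serotonin signalling genes did not pass (camera adjusted p = 0.192), with the serotonin receptor Htr4 at 1.39 ± 0.42 and Maoa at 0.46 ± 0.30.

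NAD biosynthesis and NAD consumption lists did not pass (camera adjusted p = 0.421 and 0.617). Log2 fold changes were -0.12 ± 0.15 for Nampt, -0.37 ± 0.13 for Nmnat1, 0.0059 ± 0.18 for Nmrk1, 0.37 ± 0.22 for Naprt, -0.52 ± 0.21 for Afmid of the tryptophan route to NAD, -0.40 ± 0.28 for Cd38 and 0.80 ± 0.77 for Nnmt. Naprt passed only in voom with library weights, at 0.59 (adjusted p = 0.048; 0.048 to 0.998 over all alternatives). Those of the other genes always followed were 0.15 ± 0.52 for Muc2, 1.15 ± 0.60 for Slc26a3, -0.73 ± 0.70 for Il1b and 0.27 ± 1.05 for S100a8, and Lgr5 was at 2.89 ± 1.32 CPM in CAC_FPL. The count of 0 genes became 4 without CAC_FPL replicate 4 and 3 without CAC_FPL replicate 5. Hba-a1, Hba-a2 and Hbb-bs passed without either and Npas2 without CAC_FPL replicate 4 (adjusted p = 0.0171, edgeR; 0.0171 to 0.998 over all alternatives). At an unadjusted p below 0.05 there were 995 genes where chance gives 754, DESeq2 called 21 genes and voom with library weights 672. Named genes among the 672, besides Naprt, were Hbb-bt, Ccr2, Dpp9, Cdkl2, Tomm6, Npas2, Ccng1, Mdm2, Maoa and Bhlhe41. In 0.252% of genes the groups did not overlap, where chance gives 0.433%.

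**Figure D5:**
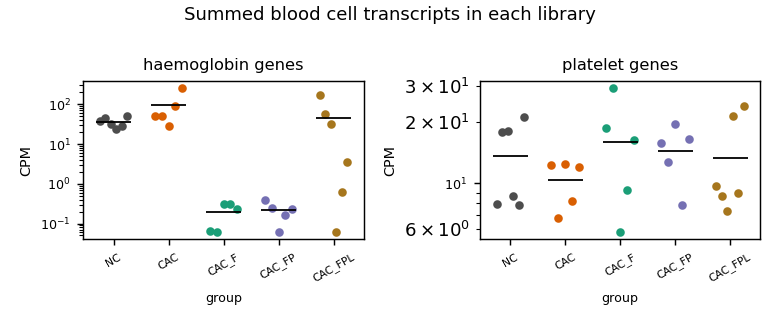
Summed CPM of haemoglobin genes and of platelet genes in each library on log axes, 1 point per library, with group means as lines. Haemoglobin transcripts stayed between 0.0615 and 0.383 CPM in CAC_F and CAC_FP and between 24.2 and 254 CPM in NC and CAC, while platelet transcripts averaged 15.8 CPM in CAC_F and 10.3 CPM in CAC.

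CAC_F libraries enter the comparisons with CAC and with CAC_FP with opposite sign, so an opposite relation arises without any effect. Of the 5902 genes called in CAC_F against CAC, 89.4% had the opposite sign in CAC_FP against CAC_F, where 20 simulations of unchanged groups sharing CAC_F gave 77.0% to 79.0%. With the CAC_F libraries divided between the comparisons the share was 79.5% of 5511 genes or 72.8% of 3926 genes, where 20 simulations divided in this way gave 48.7% to 51.1% and 48.6% to 51.9%. For CAC_FP against CAC_F and CAC_FPL against CAC_FP, 54.5% of the 200 genes with the smallest p had opposite signs, where simulation gave 90.5% to 96.5%. All these simulations drew each gene independently. Variation that genes share between libraries is not in their ranges, which are thus too narrow to say whether a share departs from chance.

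The 5 further comparisons set the treated groups against CAC, NC and one another. CAC_FP differed from CAC in 2802 genes, 1460 higher and 1342 lower. Of these 2439 were also called in CAC_F against CAC, 1340 higher and 1099 lower in both, where independent lists would share 277 and 270.6. Both comparisons use the CAC libraries, so some agreement arises without any effect. Of the 5902 genes 98.3% had the same sign in CAC_FP against CAC, where 20 simulations of unchanged groups sharing CAC gave 76.9% to 79.1% and 0 shared calls. The covariance of the log2 fold changes was 0.641, against 0.0627 in simulation. With the CAC libraries divided between the comparisons the same-sign share was 96.7% of 2083 genes or 87% of 5705 genes, where simulations so divided gave 48.2% to 52.3% and 48.9% to 50.6%. These tests of agreement, and the simulations with divided libraries, were added after the results were seen. Genes were again simulated as independent, so the simulated ranges and the 0 shared calls leave out variation that genes share between libraries. The count for CAC_FP against CAC was 1584 without CAC replicate 4, 1731 without CAC replicate 5, 1602 without CAC_FP replicate 2, 1515 without CAC_FP replicate 3, 1498 with the smooth muscle covariate and 5187 with library weights. In CAC_FP against CAC the p53 response list had 15 of 26 members higher (camera adjusted p = 3.66e-09; adjusted p = 0.246 with an estimated correlation) and the smooth muscle list 14 of 16 lower (camera adjusted p = 1.12e-09; adjusted p = 0.408 with an estimated correlation). CAC_FPL differed from CAC_F in 1838 genes, 1077 higher and 761 lower. It had 12 of 26 p53 response genes lower (camera adjusted p = 1.61e-09; adjusted p = 0.239 with an estimated correlation) and 10 of 21 inflammatory genes lower (camera adjusted p = 1.77e-06; adjusted p = 0.721 with an estimated correlation). That count was 614 without CAC_F replicate 1, 426 without CAC_F replicate 2, 593 without CAC_FPL replicate 1, 617 without CAC_FPL replicate 2, 976 without CAC_FPL replicate 3, 743 with no filter, 3457 with library weights and 0 with only these groups in the fit (edgeR; 3588 genes at an unadjusted p below 0.05).

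Against NC, CAC_F differed in 6976 genes (3409 higher, 3567 lower), CAC_FP in 4002 (2121 higher, 1881 lower) and CAC_FPL in 1068 (664 higher, 404 lower). Proliferation genes were higher in 27, 26 and 5 of 28 members, goblet cell genes lower in 14, 11 and 6 of 17, and NAD biosynthesis genes higher in 2, 2 and 1 of 14 and lower in 4, 0 and 0. The camera adjusted p of the NAD biosynthesis list was 0.259, 0.914 and 0.707. Proliferation had camera adjusted p of 3.56e-13, 4.37e-15 and 1.62e-10 (adjusted p = 0.563, 0.329 and 0.401 with an estimated correlation) and goblet cells of 1.49e-08, 3.05e-08 and 3.44e-10 (adjusted p = 0.563, 0.329 and 0.309 with an estimated correlation). The tuft cell list in CAC_FPL against NC, with 6 of 9 members lower, was called with a preset and with an estimated correlation (camera adjusted p = 1.4e-10; adjusted p = 0.0137 with an estimated correlation). The count for CAC_FPL against NC was 652 without NC replicate 1, 628 without NC replicate 3, 621 without NC replicate 4, 1899 without CAC_FPL replicate 3, 494 without CAC_FPL replicate 4, 572 without CAC_FPL replicate 5 and 632 without CAC_FPL replicate 6.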

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

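The per-library measures and genes examined for single libraries far from the rest of their group, and the tests of reads divided between haemoglobin paralogs, of time of day at collection and of squamous epithelium, were chosen after the results were seen.

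Haemoglobin transcripts were at 0.197 ± 0.126 CPM (SD, n = 5) in CAC_F and 0.218 ± 0.118 CPM (n = 5) in CAC_FP, against 94.8 ± 91.8 CPM (n = 5) in CAC and 36.5 ± 10.4 CPM (n = 6) in NC, and ran from 0.0621 to 174 CPM in CAC_FPL, which also received FOLFOX. Less residual blood in the segment predicted platelet transcripts below 0.1 of their CAC level, but the ratio of CAC_F to CAC was 1.53. Platelet transcripts did not follow haemoglobin between libraries. They were at 12.0 CPM in CAC replicate 5 and 12.4 CPM in CAC replicate 3, where haemoglobin was at 254 and 28.2 CPM. Whether they measure residual blood was not tested, so the ratio argues against this as the whole cause only if they do. Reads divided between paralogs are argued against by the sum over all haemoglobin genes, at 0.00208 of its CAC level. Shared reads appeared to be counted at each copy, so this explanation was unlikely beforehand and the sum may hold a read more than once. Fewer reticulocytes in the blood, the young red cells that carry globin RNA and whose supply depends on dividing marrow cells, was set in advance to need erythroid genes outside the globins lower in every CAC_F than in every CAC library, which was not found, as the groups overlapped at a ratio of 0.492. The sums behind that ratio were 4 to 34 counts per library, too near the floor to exclude anything, a reading made after the value was seen, so a loss of reticulocytes after FOLFOX may still be among the causes.

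Clock genes differed between CAC and NC, with Cry1 called and Bmal1 at a log2 fold change of 1.37 ± 0.29. A share of smooth muscle in the segment is argued against, since Cry1 stayed at -0.78 ± 0.12 (SE; adjusted p = 0.016, edgeR; 2.04e-06 to 0.231 over all alternatives) with the smooth muscle score as a covariate. Under a different time of day at collection, Bmal1, Clock, Npas2 and Nfil3 would move against the 10 genes of the other arm. These were Per1, Per2, Per3, Dbp, Tef, Hlf, Ciart, Nr1d1, Nr1d2 and Bhlhe41. Cry1 is in neither arm, so its fall did not enter this test. The arms had mean log2 fold changes of 0.78 and -0.72, a difference of 1.5 (exact p = 0.001 over 1001 divisions of the 14 genes, the smallest they can give). The genes had been looked at before this test, and genes are not independent replicates. A different time of day may therefore account for the pattern in these 14 genes, and it cannot be separated from an effect of neoplasia, since each would coincide with the groups.

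CAC replicate 2 and CAC_FPL replicate 3 lay apart on the second principal component, at -56.8 and -73.5, and held 7300 and 19261 counts of Hoxb13 and 550 and 3159 of Hoxd13, genes of the most distal gut, where no other library exceeded 363 and 58. A more distal segment was set in advance to need Hoxa13, Hoxd11 and Hoxd12 above all other libraries in both, and 0 of these 3 genes were, with Hoxd11 at 1.16 and 1.24 CPM where others reached 9.77 CPM. That bound was too strict, as seen only afterwards: Hoxa13, at 37.2 and 56.4 CPM, missed it by NC replicate 4 at 38.8 CPM alone, and Hoxd12 had at most 30 counts, so a more distal segment may still be the cause. Anal squamous epithelium as a cause shared by both is argued against by the sum of Krt5, Krt14 and Trp63. In the lower of the pair it was 0.466 of the highest of the other libraries, CAC_F replicate 2 at 7.47 CPM. In CAC replicate 2 the sum was 4.17 CPM, where the rest of CAC had 0.0305 to 1.92 CPM. Some squamous tissue in that library is thus not excluded, and no further explanation was tested. Without both libraries the counts were 1112 for CAC_FPL against CAC_F and 2031 for CAC_FPL against NC.

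Of 94 groups of values examined, 17 held a library far from the rest by Dixon's gap-to-range ratio. The bound used gives about 1 in 20 groups by chance for independent normal values. CPM values are skewed and the genes were chosen after the results were seen, so the count cannot be set against that rate. The total in units of 1e6 counts was 77.2 in CAC_F replicate 5 and 61.4 to 64.9 in the rest of its group. On the first principal component CAC replicate 2 lay at -14.0 (others -55.2 to -43.8) and CAC_FP replicate 4 at -0.917 (others 38.2 to 52.9). On the second, CAC_F replicate 2 lay at -22.05 (others -9.42 to -4.29) and CAC_FPL replicate 3 at -73.5 (others 9.06 to 31.3). Naprt was at 31.2 CPM in CAC replicate 2 (others 45.0 to 50.4) and at 47.0 CPM in CAC_FP replicate 4 (others 26.4 to 31.3). Nampt was at 149 CPM in CAC_FPL replicate 6 (others 83.5 to 97.2), and Mki67 at 338 CPM in CAC replicate 2 (others 159 to 209). Csf3 was at 0.0803 CPM in NC replicate 4 and 0.184 CPM in CAC replicate 3, the other libraries of both groups being at 0, and at 71 CPM in CAC_FP replicate 1 (others 0.0557 to 15.2). Clca1 was at 21300 CPM in CAC replicate 3 (others 4690 to 8440). Hbb-bs was at 99.7 CPM in CAC replicate 5 (others 11.8 to 36.6) and 69 CPM in CAC_FPL replicate 1 (others 0 to 22.8). Reg3b was at 3960 CPM in CAC_FPL replicate 5 (others 6.95 to 1050), and Ptgs2 at 10.2 CPM in NC replicate 5 (others 3.47 to 5.91).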

How the results depend on the processing

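The settings voom with quantile normalization, DESeq2 and the omission of CAC replicate 2 with CAC_FPL replicate 3 were chosen after the data were seen, as was the use of limma on log2(FPKM + 1), the test planned for FPKM alone, beside counts, and the others were planned. Of 199 results for a named gene in a comparison, 86 were called, and 79 of these kept their direction and their side of the threshold in every alternative. The other 7 dropped below the threshold in at least 1 alternative without a change of direction, and of the 113 that were not called 42 passed in at least 1. A depth of at least 56687812 counts per library leaves the spread between mice, not counting, as the limit for most genes, whereas Csf3, haemoglobin genes and Lgr5 were near the floor in at least 1 group. Except where fewer genes or libraries entered a fit, the cause of the differences below was not tested.

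For CAC against NC the 1 gene called became 2 with voom and quantile normalization, 10 with library weights, 0 with a replicate block, 0 with only these groups in the fit, 3 with limma on log2(FPKM + 1), 2 with limma on log2(FPKM + 0.1), 2 with quantile-normalized FPKM and 41 with DESeq2. Leaving out 1 library gave 0 (without NC replicate 2) to 4 (without NC replicate 5). At an unadjusted p below 0.05 the replicate block had 1320 genes and the fit of only these groups 1547, both by edgeR. Replicate numbers were taken to pair libraries only if every same-numbered correlation of a comparison was over 0.1, which held in none. They ran from -0.345 to -0.0203 for CAC with NC, 0.0163 to 0.258 for CAC_F with CAC, -0.147 to 0.36 for CAC_FP with CAC_F and -0.486 to 0.0615 for CAC_FPL with CAC_FP. Over 0.1 were 0, 4, 4 and 0 of 5, and 0, 3, 2 and 0 of 5 libraries correlated best with their own number, so a partial pairing in CAC_F with CAC and CAC_FP with CAC_F stays possible. With the block the adjusted p of Cry1 in CAC against NC was 0.0671 (edgeR), and in CAC_FPL against CAC_FP the camera adjusted p was 0.0923 for T cells and 0.0943 for B and plasma cells.

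For CAC_F against CAC the 5902 genes became 3708 with a mean FPKM of at least 5, where fewer genes were tested, and 4905 to 6102 with 1 library left out. Limma on log2(FPKM + 1) called 5713 genes, 59.1% of them higher where edgeR had 48.5%. For CAC_FP against CAC_F the 0 genes became 38 with library weights, 2 with quantile-normalized FPKM and 238 with DESeq2, and 0 to 616 with 1 library left out. For CAC_FPL against CAC_FP the 0 genes became 672 with library weights and 21 with DESeq2, and 0 to 4 with 1 library left out. These pairs had 2401 and 995 genes at an unadjusted p below 0.05 by edgeR.

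For CAC_FP against CAC the 2802 genes became 5187 with library weights, 1498 with the smooth muscle covariate and 1515 to 3448 with 1 library left out. For CAC_FPL against CAC_F the 1838 genes became 743 with no filter, 3457 with library weights, 0 with only these groups in the fit (3588 at an unadjusted p below 0.05, edgeR), 1112 without CAC replicate 2 and CAC_FPL replicate 3, and 426 to 2540 with 1 library left out. For CAC_F against NC the 6976 genes became 4286 with a mean FPKM of at least 5 and 5981 to 7036 with 1 library left out. For CAC_FP against NC the 4002 genes became 2584 with a mean FPKM of at least 5, 6669 with library weights and 2801 to 4242 with 1 library left out. For CAC_FPL against NC the 1068 genes became 613 with no filter, 709 with a mean FPKM of at least 5, 622 with only these groups in the fit, 1799 with DESeq2, 2031 without CAC replicate 2 and CAC_FPL replicate 3, and 494 to 1899 with 1 library left out. The share of called genes that were higher also moved with limma on log2(FPKM + 1), to 68% from 52.1% for CAC_FP against CAC, 64.9% from 48.9% for CAC_F against NC, 76% from 53% for CAC_FP against NC and 78.7% from 62.2% for CAC_FPL against NC. With log2(FPKM + 0.1) the median of all genes shifted to 0.112, 0.116 and 0.109 in CAC_F, CAC_FP and CAC_FPL against NC, from -0.026, -0.0291 and -0.00327. With voom and quantile normalization the share was 46.7% from 58.6% for CAC_FPL against CAC_F and 50.6% from 62.2% for CAC_FPL against NC, and with library weights 51.9% for the latter.

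With an estimated correlation camera called 0 lists in CAC against NC, CAC_F against CAC, CAC_FP against CAC_F, CAC_FPL against CAC_FP, CAC_FP against CAC, CAC_FPL against CAC_F, CAC_F against NC and CAC_FP against NC, and 1 in CAC_FPL against NC, where the preset correlation had called 19, 15, 17, 10, 18, 9, 16, 16 and 20. Fry called 0 in CAC against NC, 1 in CAC_FP against CAC_F, 0 in CAC_FPL against CAC_FP, 2 in CAC_FPL against CAC_F and 9 in CAC_FPL against NC. Lists called in CAC against NC became 10 with a mean FPKM of at least 5, and those in CAC_FPL against CAC_F became 17 with no filter and 14 with the smooth muscle covariate.

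The share of opposite signs between CAC_F against CAC and CAC_FP against CAC_F was 79.5% or 72.8% with CAC_F divided, down from 89.4%, while the value without any effect went from 77.0% to 79.0% down to 48.6% to 51.9%. That between CAC_FP against CAC_F and CAC_FPL against CAC_FP, 54.5%, became 53% with median-ratio factors and 46% or 13.5% with CAC_FP divided, where simulations without any effect gave 46.5% to 57% and 42% to 56.5%. The values without any effect hold for genes simulated as independent, and shared variation would widen them.

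Some genes that were not called changed sign, given here as log2 fold changes with the range over fits that leave out 1 library. In CAC against NC, Nmnat1 was at 0.0204 with limma on log2(FPKM + 1) and 0.0280 with log2(FPKM + 0.1), and Muc2 at 0.0199 with voom and quantile normalization. Naprt was at 0.0151 without CAC replicate 2 and CAC_FPL replicate 3, and with 1 library left out Naprt ran from -0.167 to 0.0151 and Cd38 from -0.286 to 0.0547. In CAC_F against CAC, Nnmt was at 0.571 and Muc2 at 0.197 with the smooth muscle covariate, and Nnmt ran from -0.565 to 0.322. In CAC_FP against CAC_F, Nmrk1 was at -0.00285 with library weights and Nampt ran from -0.0603 to 0.116. Slc26a3 was at -0.00912 with no filter, -0.00194 with median-ratio factors, -0.473 with library weights, -0.0102 with the covariate, -0.00199 with DESeq2 and -0.00539 without CAC replicate 2 and CAC_FPL replicate 3, and ran from -0.429 to 0.393. In CAC_FPL against CAC_FP, library weights gave 0.359 for Lgals2, -0.153 for Atp12a and -0.471 for S100a8. Without CAC replicate 2 and CAC_FPL replicate 3, Atp12a was at -0.458 and S100a8 at -0.481. S100a8 was at -0.0758 with voom and quantile normalization and -0.0201 with limma on log2(FPKM + 0.1), and Muc2 at -0.124 with the covariate. Nmrk1 was at -0.00471 with no filter, -0.00750 with limma on log2(FPKM + 1) and -0.00820 with log2(FPKM + 0.1). With 1 library left out Lgals2 ran from -4.28 to 0.872, Atp12a from -0.458 to 5.24, Nmrk1 from -0.115 to 0.115, Muc2 from -0.118 to 0.438 and S100a8 from -0.481 to 0.591.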

Other observations

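The mean signed change used to follow genes into the other groups and its simulations were chosen after the results were seen, as was the choice of which of the gene lists fixed in advance are described here, and the divisions of the libraries were set before their results.

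Further lists held called members in CAC_F against CAC, where 39.1% of all genes were called. Of the 6 lists given here 5 did not pass by camera, so their members are listed as single genes. Of 15 immediate early genes 7 rose (camera adjusted p = 0.00423; adjusted p = 0.664 with an estimated correlation), with log2 fold changes of 3.07 ± 0.50 (SE, n = 5 and 5) for Ier3 and 5.78 ± 0.97 for Fosl1, a partner of Jun in the AP-1 factor. Of 19 tight junction and adhesion genes 5 rose and 2 fell (camera adjusted p = 0.54), with Cldn4 at 3.13 ± 0.47. Of 22 fluoropyrimidine and platinum handling genes 9 rose and 2 fell (camera adjusted p = 0.183), with Uck2, a uridine kinase, at 0.84 ± 0.17 and Ercc1, which excises platinum adducts from DNA, at 1.29 ± 0.31. Of 18 fibroblast and matrix genes 4 rose and 2 fell (camera adjusted p = 0.487), with Mmp2 at 1.35 ± 0.29 and Pdgfra at 1.31 ± 0.30. Of 16 Wnt target and crypt base genes 4 rose (camera adjusted p = 0.128), with the Wnt antagonist Wif1 at 1.99 ± 0.28 and Myc at 1.73 ± 0.32. Of 20 absorptive colonocyte genes 4 fell (camera adjusted p = 0.183), with Guca2a at -1.93 ± 0.38 and Cyp2c55 at -4.67 ± 1.09.

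The genes that differed after FOLFOX were followed into the other groups, with CAC as the reference throughout. For 5511 genes chosen on CAC_F replicates 1 and 2, the mean log2 fold change against CAC, signed by the chosen direction, was 0.72 in CAC_F replicates 3 to 5, 0.56 in CAC_FP, 0.37 in CAC_FPL and -0.037 in NC. For 3926 genes chosen on CAC_F replicates 3 to 5 it was 1.11 in replicates 1 and 2, 0.77 in CAC_FP, 0.50 in CAC_FPL and -0.024 in NC. Since the same CAC libraries chose the genes, 20 simulations of unchanged groups gave 0.134 to 0.162 in the former case and 0.17 to 0.207 in the latter. Genes were independent in these simulations, so variation that genes share between libraries is not in these ranges. With CAC divided as well, so that the libraries measured had not chosen the genes, the values were 0.59 to 1.57 in the other CAC_F libraries, 0.41 to 1.09 in CAC_FP, 0.23 to 0.66 in CAC_FPL and -0.25 to -0.0095 in NC, over 4 divisions with 582 to 5540 genes. The difference between CAC_FP and CAC_FPL on these genes was not tested.

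The libraries of each comparison were divided in 25 ways into groups of the same sizes, the real one included. A share of 1 of 25 was thus the smallest possible, and it was not adjusted over the 9 comparisons. Only the real division gave as many genes for CAC_F against CAC (5902 genes, highest other 2535), CAC_FP against CAC (2802, highest other 0), CAC_F against NC (6976, highest other 0), CAC_FP against NC (4002, highest other 0) and CAC_FPL against NC (1068, highest other 9). The same was found for CAC against NC, but with 1 gene against a highest other of 0 and a call lost in 6 alternatives, which does not exclude chance. Chance could not be excluded for CAC_FPL against CAC_F, where 2 of 25 divisions gave as many as the real 1838 genes (highest other 1941). For CAC_FP against CAC_F (0 genes by edgeR, highest other 3) and CAC_FPL against CAC_FP (0 genes by edgeR, highest other 1) the divisions decide nothing, since all 25 must give at least 0 genes. At an unadjusted p below 0.05 these had 2401 and 995 genes, and DESeq2 called 238 and 21.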
